A study of Homo sapiens with 12 samples.

How the data were processed

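Transcript levels were measured on 12 Illumina BeadChip arrays, 3 for each of 4 cell populations derived from H9 human embryonic stem cells. Per the labels, the stem cells were at passages 35 to 45 and 0.55 µg of total RNA per sample was turned into biotinylated cRNA and hybridised. The authors exported the bead summaries from GenomeStudio 2011.1. The deposited signal columns hold intensity on a linear scale, not normalized between arrays and with no background subtracted, from 49.5 to 61959. The detection p-value beside each signal, as deposited by the authors, was computed as the share of negative-control beads at or above it, in steps of 1 in 770. The deposited value table of the authors is in log2 and equals a quantile normalization of the log2 signals over the 12 arrays, with a largest difference of 0.000193 and the same median of 7.05 on every array. These units were tested on the values themselves.

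The linear signals were used. Background was estimated from the detection p with the neqc function of limma 3.58.1 in R 4.3.3, an offset of 16 was added, and the arrays were quantile normalized and put on the log2 scale. Of 47322 probes, 30112 carried 1 gene symbol, 8 carried several genes and 17202 carried none. The symbols were checked against the annotation by Entrez ID, which matched 30073 probes and changed 0 symbols. The 39 unmatched probes kept the symbol given with the array. A probe was kept if it was detected, at a detection p under 0.01, on all 3 arrays of at least 1 group, which 18003 probes were, 14599 of them with 1 symbol. Each gene was then represented by its probe with the highest mean over the 12 arrays, which left 11230 genes. For 2786 genes this was a choice among several detected probes. A gene is identified by its symbol, and no genome positions are given because no build was used.

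Each comparison was a contrast in 1 limma model (lmFit, then eBayes with an intensity trend) over all 12 arrays with 1 coefficient per population, which leaves 8 residual degrees of freedom. A gene was called when its Benjamini-Hochberg adjusted p over the 11230 genes was under 0.05. The 3 main comparisons set the sorted populations against each other, and 3 secondary ones set each of them against neural rosettes. Values are given as the mean ± SD of normalized log2 intensity over 3 arrays, and differences are in log2. Where a gene was detected on no array of the dimmer population, the change is given as a lower bound, "at least N-fold". That bound sets each such array at the lowest normalized signal of any detected probe on that array, or at the gene's own value where this was higher.

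The samples, the comparisons, the test, 22 gene lists, the alternatives and the rule for named genes were chosen before the data were examined. For each main comparison the rule takes, among called genes whose 3 arrays of 1 population all lie above the 3 of the other, the 8 with the largest increase and the 8 with the largest decrease. Secondary comparisons take 5 and 5. The rule adds every gene of the sort antigen list and, for each list, up to 4 measured members with the largest absolute change. The lists were sort antigen genes; CNS neural progenitor; anterior forebrain and eye field; midbrain, hindbrain and HOX; neural crest; Schwann cell and melanocyte lineage; sensory and autonomic neuron lineage; neuron differentiation; early mesoderm; mesenchyme and extracellular matrix; smooth muscle and contractile; skeletal muscle, cartilage and bone; pluripotency; surface ectoderm and epithelium; endoderm; endothelium and blood; cell cycle; immediate early and dissociation stress; hypoxia and glycolysis; BMP and TGF-beta response; WNT response; and NOTCH pathway. Some genes stand in more than 1 list, so the lists are not independent. Among them are PAX6, OTX2 and LHX2 in the progenitor and the anterior list, HES5 in the progenitor and the NOTCH list, and DLL3 in the neuron differentiation and the NOTCH list. Others are MSX1 and MSX2 in the crest and the BMP list, EDNRB in the crest and the Schwann cell list, and TWIST1 in the crest and the mesenchyme list. PRRX1 is in the mesoderm and the mesenchyme list, TGFBI in the mesenchyme and the BMP list, and NGFR in the antigen and the crest list.

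Lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01 between genes, which compares a list with all other genes. The 120 tests of 20 lists in 6 comparisons form 1 Benjamini-Hochberg family. At the preset, 58 lists were called, and with a correlation estimated from the data 1 of these remained, the midbrain, hindbrain and HOX list between p75+HNK1+ and PSA-NCAM-negative cells. The median of a list is also given with its undetected members at their bound, where it differs. Changes of both other populations against the shared PSA-NCAM-positive arrays were correlated across genes. Beside them stand 100 simulated draws in which unchanged groups shared 1 control group. All groups of a draw were made from residuals of arrays drawn at random, with random signs. The simulated controls were thus not fixed to be the PSA-NCAM-positive arrays.

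The procedure was tested on simulated data with 200 changed genes per comparison. Between PSA-NCAM-negative and PSA-NCAM-positive cells it recovered 33% of true log2 changes of 1 and 82% of those of 2, and 3.36% of its calls were false. In the other comparisons it recovered 22% to 45% and 80% to 88%, with 2.22% to 5.98% of calls false, and no comparison gave a call of the wrong sign (0 calls). In the simulation an unchanged list reached an unadjusted camera p of 0.0145 in 1 of the 6 comparisons. The simulated noise was independent between genes, so the effect of correlation within lists was not tested by it.

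Alternatives were the normalization (log2 quantile without background correction, median scaling after the same background correction, and the value table of the authors), no filter on dim probes, detection on all 12 arrays, every probe on its own, only the 6 arrays compared, the replicate number as a block, a change of at least 2-fold, an estimated correlation for the lists, and leaving out each array in turn. The replicate number is the order in which the samples of a population are listed, since the labels give no replicate number that the populations share. Array weights were added after the data were seen. Probes with no single symbol were left out of the gene counts because they cannot be placed in a list. The figures were drawn with matplotlib 3.10.9. Sequence-level and surface-antigen measurements were not used here.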

Results

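Gene expression was measured in 12 samples of 4 cell populations, 3 samples each, all derived from H9, an established line of human embryonic stem cells. Neural rosettes, the rings of neuroepithelial cells that form when stem cells take a neural fate, were taken on day 16. The other 3 populations were isolated from such rosettes by surface antigens. PSA-NCAM, the polysialylated form of the neural cell adhesion molecule, marks migrating and immature neural cells, and cells with and without it form the PSA-NCAM-positive and PSA-NCAM-negative populations. The p75+HNK1+ population carried p75, the neurotrophin receptor encoded by NGFR, and HNK1, a sugar epitope made with the enzyme encoded by B3GAT1, a pair of antigens used to isolate neural crest cells. The neural crest is the migratory cell population that leaves the dorsal neural tube and forms peripheral neurons, glia, pigment cells and much of the mesenchyme of the face.

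Between 16335 and 18378 of the 47322 probes were detected per array, and the mean raw signal ran from 658 to 993. PSA-NCAM-negative replicate 2 was the lowest by both measures. The number of arrays limits the precision, and p-values measure only the spread between these samples, since nothing in the labels says whether the replicates were separate cultures.

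The arrays fell into 2 sets. Across genes, neural rosettes and PSA-NCAM-positive cells correlated with each other at a mean r of 0.947, and PSA-NCAM-negative with p75+HNK1+ cells at 0.962. Within the populations the mean r ran from 0.944 to 0.980. Correlations across the 2 sets were lower: 0.881 between PSA-NCAM-positive and PSA-NCAM-negative cells, 0.917 between PSA-NCAM-positive and p75+HNK1+ cells, 0.872 between rosettes and PSA-NCAM-negative cells, and 0.907 between rosettes and p75+HNK1+ cells. Genes are not independent replicates, so these values describe the arrays and are no test. The first principal component, with 53.4% of the variance, separated the same 2 sets.

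**Figure D1:**
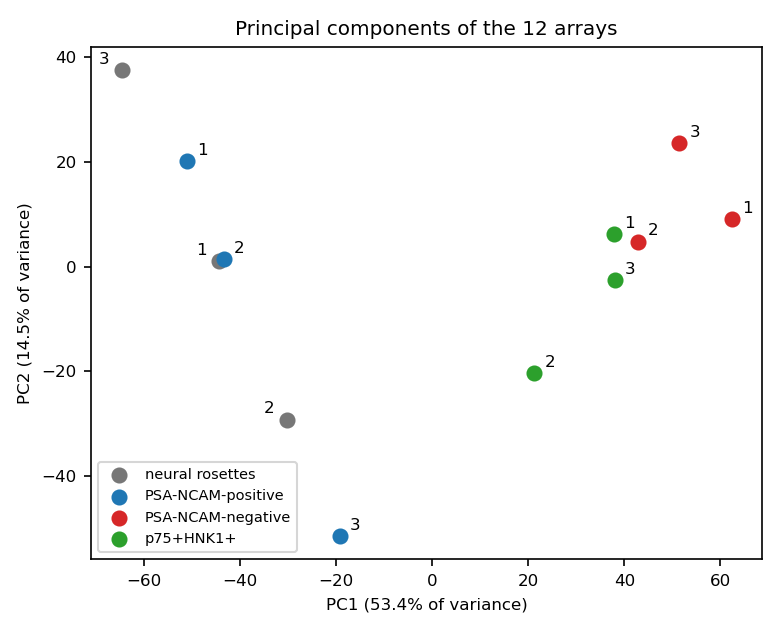
Principal components of normalized log2 intensity of 11230 genes on 12 arrays; each point is 1 array, coloured by population and labelled with its replicate number, with component 1 (53.4% of the variance) on the horizontal and component 2 (14.5%) on the vertical axis. Rosettes and PSA-NCAM-positive arrays lie apart from PSA-NCAM-negative and p75+HNK1+ arrays along component 1.

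The first comparison asks how rosette cells with and without PSA-NCAM differ. Among the genes with the largest increase in PSA-NCAM-negative cells were LHX8, BARX1, LHX6 and TBX3. LHX8, which patterns the first pharyngeal arch, was at 10.80 ± 0.61 (SD, n = 3) against 4.93 ± 0.59, at least 26.8-fold higher (adjusted p = 2.62e-06). BARX1, a homeobox gene of tooth and jaw mesenchyme, was higher by 5.11 in log2 (0.000212), LHX6 by 5.06 (2.88e-05), and TBX3, a T-box factor, at least 25.9-fold (0.000296). Among those with the largest decrease were WNT3A and HES5. WNT3A, a signal of the dorsal neural tube, was at 5.14 ± 0.61 against 12.24 ± 0.34, at least 67.2-fold lower (1.69e-06), and the NOTCH effector HES5 was at 6.12 ± 0.55 against 12.96 ± 1.57, a difference of -6.83 (3.94e-05).

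Among the genes behind the sort antigens, NGFR was higher in PSA-NCAM-negative cells, at 8.57 ± 0.22 against 6.59 ± 0.08 (log2 difference 1.98, adjusted p = 0.000783). B3GAT1 was lower, at 7.66 ± 0.20 against 9.94 ± 0.24 (-2.28, 0.000149), and so was ST8SIA2, a polysialyltransferase that makes the PSA-NCAM epitope, at 9.32 ± 0.42 against 10.67 ± 0.14 (-1.35, 0.00305). NCAM1, the protein that carries it, differed by -0.68 (0.293), ST8SIA4 by -0.94 (0.382) and CHST10, a sulfotransferase of the HNK1 epitope, by -0.16 (0.707), and none of these 3 was called. As a list of 6 measured genes, with 1 higher, 2 lower and 3 not called, the antigen genes were not called (median -0.81, adjusted p = 0.189), and the counts adjusted over the list alone were the same.

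Genes of central nervous system (CNS) progenitors were lower as a group in PSA-NCAM-negative cells. Of 17 measured, 14 were lower, 1 was higher and 2 were not called, and adjusted over the list alone 14 were lower and 1 higher (median -3.04, camera adjusted p = 8.88e-11, and adjusted p = 0.0536 with an estimated correlation). SOX3, a factor that keeps neural progenitors undifferentiated, was at 6.90 ± 1.06 against 12.88 ± 0.27 (-5.98, 2.62e-06). PAX6 and OTX2, which pattern the forebrain and eye, were at least 21.8-fold and at least 16.4-fold lower (2.62e-06 for each). The 1 higher member was the homeobox gene MEIS2, a cofactor of other homeobox proteins (1.73, 0.0316), which was named after its value was seen. Of 8 anterior forebrain and eye field genes, 7 were lower and 1 was not called, also when adjusted over the list alone (median -2.64, or -2.12 with undetected genes at their bound, adjusted p = 4.19e-07, and adjusted p = 0.0569 with an estimated correlation). EMX2, a cortical patterning gene, differed by -3.25 (0.00113) and FEZF2, a gene of the forebrain, was at least 3.89-fold lower (0.000804).

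Neuron differentiation genes were lower with them. Of 18 neuron differentiation genes, 15 were lower, 0 higher and 3 not called, and 16 were lower adjusted over the list alone (median -2.21, or -1.92 at bounds, adjusted p = 8.96e-13, and adjusted p = 0.0656 with an estimated correlation). They included STMN2, a microtubule regulator of growing axons (-4.86, 0.000197), the neurofilament gene INA (-4.00, 0.000612) and the neuronal RNA-binding gene ELAVL3 (-3.82, 0.000533). In the NOTCH pathway, 12 of 17 genes were lower, 0 higher and 5 not called, with 14 lower and 1 higher adjusted over the list alone (median -2.20, adjusted p = 2.95e-11, and adjusted p = 0.0569 with an estimated correlation). The target HES4 differed by -4.55 (2.62e-06), the ligand DLL1 by -3.92 (1.76e-05), and MFNG, which modifies NOTCH receptors, was at least 6.76-fold lower (3.50e-05). Of 16 WNT response genes, 8 were lower, 1 higher and 7 not called, with 10 lower and 2 higher adjusted over the list alone (median -1.57, or -1.21 at bounds, adjusted p = 2.72e-06, and adjusted p = 0.0693 with an estimated correlation). SP5, a direct WNT target, was at least 15.9-fold lower (5.88e-05), and the feedback inhibitors DKK1 and NKD1 differed by -3.59 (0.00282) and -2.78 (0.000553). The 1 higher member was WNT5A, a ligand (1.42, 0.0258), named after its value was seen.

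The neural crest list split in PSA-NCAM-negative cells. Of 24 measured genes, 8 were higher, 5 lower and 11 not called, and adjusted over the list alone 11 were higher and 8 lower. Higher members included DLX1, a homeobox gene of crest and forebrain, at 13.58 ± 0.27 against 10.41 ± 0.40 (3.16, adjusted p = 3.50e-05), and among members named after their values were seen the crest factors TFAP2A (2.30, 0.000474) and SNAI2 (1.95, 0.00459). Lower members included PAX7 (-4.91, 3.79e-05), an early border gene, the endothelin receptor EDNRB (-3.55, 0.00336) and the cadherin CDH6 (-3.44, 0.000533). The list was not called (adjusted p = 0.201), and its median (0.78, or 0.63 at bounds) and its mean (-0.10) differed in sign. With genes detected on all 12 arrays the list was called higher (1.04, 0.000235). That filter removes the SOX10 and EDNRB probes used here, which were not detected on every PSA-NCAM-negative array. Both genes were lower in these cells, so dropping such members can by itself turn the list higher.

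Mesenchyme and extracellular matrix genes were higher in PSA-NCAM-negative cells. Of 31 measured, 10 were higher, 2 lower and 19 not called, as also adjusted over the list alone (median 0.82, adjusted p = 0.00169, and adjusted p = 0.440 with an estimated correlation). PDGFRA, a growth factor receptor of mesenchyme, was higher by 2.97 (0.00646) and TIMP3, a matrix protease inhibitor, by 2.69 (0.000184), while the matrix glycoprotein gene SPARC differed by -2.29 (3.94e-05). On PSA-NCAM-negative replicate 2 this list stood 0.71 above the mean of the other arrays of its population, with 27 of 31 members above, and without that array the list was not called (median 0.39, adjusted p = 0.137).

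Of 6 surface ectoderm and epithelium genes, 4 were lower, 0 higher and 2 not called, with 5 lower and 1 higher adjusted over the list alone (median -2.40, or -2.0 at bounds, adjusted p = 0.000371, and adjusted p = 0.0569 with an estimated correlation). Over all settings the list median ran from -2.53 to -0.089. The keratin genes KRT19 (-3.70, 0.000183) and KRT8 (-3.22, 0.00175), the adhesion gene EPCAM (at least 5.11-fold lower, 1.68e-05) and the desmosome gene DSP (-1.64, 0.00310) were the lower members. Of 17 BMP and TGF-beta response genes, 5 were lower, 0 higher and 12 not called, with 8 lower adjusted over the list alone (median -1.13, or -1.05 at bounds, adjusted p = 0.000324, and adjusted p = 0.348 with an estimated correlation). They included the BMP antagonist GREM1 (-3.03, 0.000437) and the inhibitor of differentiation ID4 (at least 2.48-fold lower, 0.000523). On PSA-NCAM-negative replicate 2 this list stood 1.01 above the other arrays of its population, with 16 of 17 members above.

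Of 11 midbrain, hindbrain and HOX genes, 4 were lower, 0 higher and 7 not called, also adjusted over the list alone, and the list was called lower (median -0.08, or 0.00 at bounds, mean -1.41, adjusted p = 0.0231, and adjusted p = 0.287 with an estimated correlation). PAX8 was at least 15.8-fold lower (1.53e-05), EN2, a gene of the midbrain-hindbrain boundary, differed by -4.53 (0.000810), EN1 was at least 2.74-fold lower (0.000223) and GBX2 differed by -3.24 (0.0189). The list was not called without PSA-NCAM-positive replicate 3 (0.0551), without PSA-NCAM-negative replicate 3 (0.0513) or with no filter on dim probes (0.0855). The call of GBX2 was lost without PSA-NCAM-positive replicate 1 (0.0921), PSA-NCAM-negative replicate 1 (0.0891) and PSA-NCAM-negative replicate 3 (0.0680).

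The remaining lists were not called between PSA-NCAM-negative and PSA-NCAM-positive cells. For sensory and autonomic neuron lineage, 1 of 7 genes was higher and 2 were lower, also adjusted over the list alone (adjusted p = 0.293), PRPH, an intermediate filament of peripheral neurons, being at least 28.6-fold lower (0.000750). Early mesoderm had 2 of 5 genes higher, also adjusted over the list alone (0.410), OSR1 by 3.14 (0.00664). Of 11 smooth muscle and contractile genes, 2 were higher and 2 lower, with 2 higher and 5 lower adjusted over the list alone (0.463). In skeletal muscle, cartilage and bone 1 of 8 genes was lower, also adjusted over the list alone (0.552), ALPL, an alkaline phosphatase (-2.65, 0.000121), and the median of 0.10 and the mean of -0.39 differed in sign. Pluripotency had 1 of 7 genes higher and 1 lower, or 2 and 1 adjusted over the list alone (0.867), the latter DNMT3B, a DNA methyltransferase (-1.25, 0.000830). Endothelium and blood had 2 of 7 genes higher and 3 lower, or 2 and 4 adjusted over the list alone (0.372), with SOX18 at least 2.46-fold higher (0.00373) and CLDN5 at least 2.18-fold lower (0.00160). Hypoxia and glycolysis had 1 of 15 genes higher and 1 lower, also adjusted over the list alone (0.491), the latter the glucose transporter SLC2A1 (-1.87, 0.00106), with a list median on PSA-NCAM-negative replicate 2 that stood 1.33 above the other arrays of its population. Endoderm, with 1 gene measured and lower, and Schwann cell and melanocyte lineage, with 4 genes measured and 2 of them lower, were too small to test.

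Cell cycle and immediate early lists were not called with all arrays, but were without some of them. Of 23 cell cycle genes 0 were called by limma and the list was not called (median 0.17, adjusted p = 0.134), but it was called higher without PSA-NCAM-positive replicate 2 (0.0288) and without PSA-NCAM-negative replicate 2 (0.0378). Of 17 immediate early and dissociation stress genes, 2 were higher and 1 lower, also adjusted over the list alone, MYC, a growth regulator, among the former (2.82, 0.000686), and the list was not called (median 0.32, 0.385). It was called without PSA-NCAM-positive replicate 1 (median 0.52, with an adjusted p just under the threshold) and without PSA-NCAM-negative replicate 1 (0.0365), and on PSA-NCAM-negative replicate 2 it stood 1.18 above the other arrays of its population.

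Over all 11230 genes, 555 were higher and 1056 lower in PSA-NCAM-negative than in PSA-NCAM-positive cells, so 34.5% of the called genes were higher. With median scaling, under which the median of all genes was -0.11 instead of 0.01, 344 were higher and 1288 lower (21.1% higher). The 3 arrays of each population did not overlap for 27.3% of genes, against 10% by chance. The number of higher genes was 939 without PSA-NCAM-positive replicate 3, 345 without PSA-NCAM-negative replicate 1 and 344 without PSA-NCAM-negative replicate 3.

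**Figure D2:**
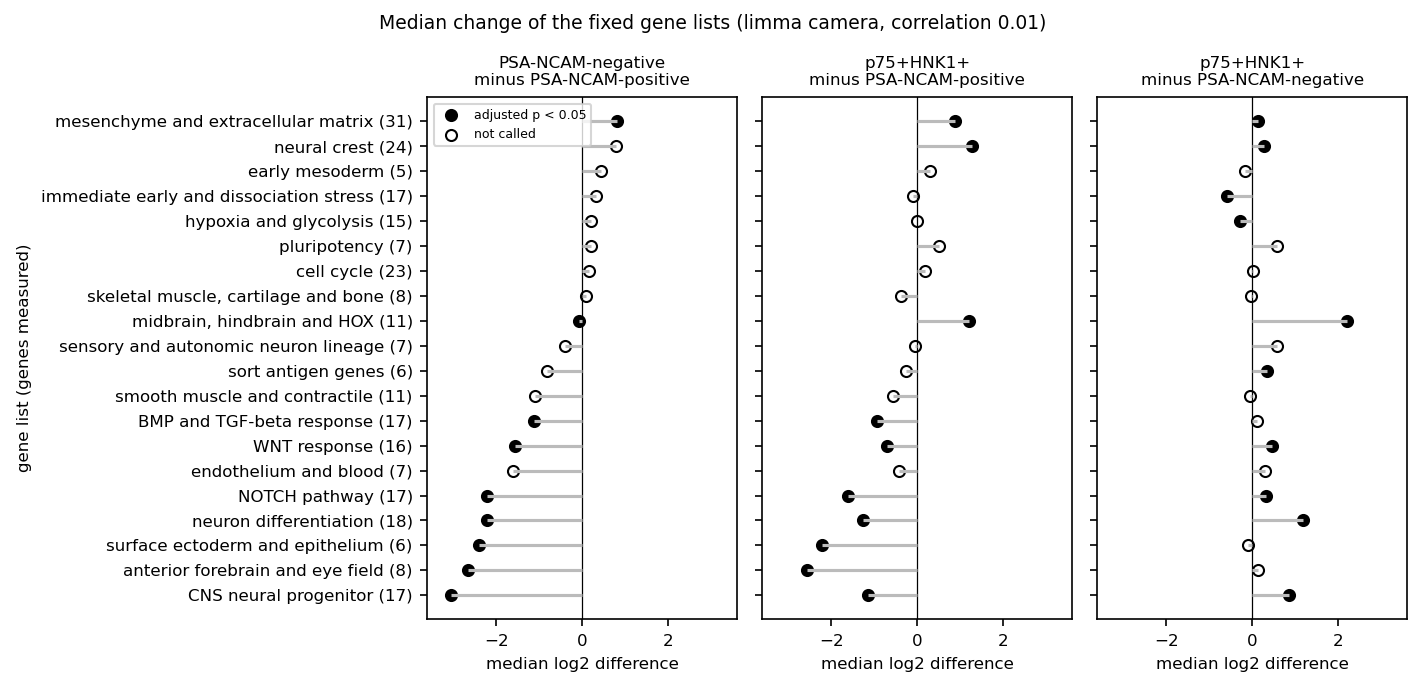
Median log2 difference of 20 gene lists in the 3 main comparisons, with the number of genes measured in brackets; filled points are lists called at an adjusted p under 0.05 by camera at its preset correlation, and open points are not called. No error bars are drawn, and with an estimated correlation only the midbrain, hindbrain and HOX list between p75+HNK1+ and PSA-NCAM-negative cells was called.

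The second comparison asks how p75+HNK1+ cells differ from PSA-NCAM-positive cells. Among the genes with the largest increase in p75+HNK1+ cells were HOX genes, which mark positions from the hindbrain to the trunk. HOXB8 was at 9.44 ± 0.29 (SD, n = 3) against 5.11 ± 0.17, at least 10.4-fold higher (adjusted p = 0.000461), HOXB7 was at least 5.01-fold higher (0.000116), and HOXC6 was higher by 3.61 (0.00328). LHX8 was at least 9.72-fold (5.90e-05) and DLX5, a homeobox gene of the pharyngeal arches, at least 7.25-fold higher (0.00552). OTX2 was at 5.05 ± 0.29 against 10.21 ± 0.48, at least 17.7-fold lower (1.01e-05), and WNT3A differed by -5.16 (1.45e-05).

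NGFR was at 8.72 ± 0.69 in p75+HNK1+ and 6.59 ± 0.08 in PSA-NCAM-positive cells (log2 difference 2.12, adjusted p = 0.00123). B3GAT1 differed by -0.71 and was not called (0.150), and neither was NCAM1 (-0.41, 0.588). ST8SIA2 was lower (-0.93, 0.0449). That call was lost without PSA-NCAM-positive replicate 1 (0.130) or 2 (0.117), without p75+HNK1+ replicate 1 (0.177), 2 (0.0725) or 3 (0.0899) and with median scaling (0.123). The antigen list, with 1 of 6 genes higher and 1 lower, or 1 and 2 adjusted over the list alone, was not called (0.720), and its median (-0.26) and mean (0.02) differed in sign. Another probe of its member ST8SIA4 differed in the opposite direction.

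Of 24 neural crest genes, 9 were higher, 3 lower and 12 not called, with 14 higher and 4 lower adjusted over the list alone (median 1.28, or 1.24 at bounds, adjusted p = 9.05e-05, and adjusted p = 0.0569 with an estimated correlation). DLX1 was higher by 2.78 (0.000210), and among members named after their values were seen TFAP2A was higher by 2.05 (0.00249) and SNAI2 by 1.92 (0.0102). PAX7 differed by -3.89 (0.000461) and PAX3, also an early border gene, was at least 2.55-fold lower (0.000524). SOX10, a factor of migrating crest and glia, was at 10.83 ± 0.38 against 8.69 ± 2.36 and was not called (2.14, 0.168), in a gene named after its values were seen. Of 31 mesenchyme and extracellular matrix genes, 7 were higher, 1 lower and 23 not called, with 12 higher and 1 lower adjusted over the list alone (median 0.89, adjusted p = 3.26e-06, and adjusted p = 0.223 with an estimated correlation). TIMP3 was higher by 2.89 (0.000249) and LOX, which crosslinks collagen, by 2.49 (0.00430), while SPARC differed by -2.31 (0.000116).

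The midbrain, hindbrain and HOX list was higher in p75+HNK1+ cells. Of 11 genes, 6 were higher, 2 lower and 3 not called, with 6 higher and 3 lower adjusted over the list alone (median 1.19, or 1.00 at bounds, adjusted p = 0.00963, and adjusted p = 0.228 with an estimated correlation). Over all settings the list median ran from 0.175 to 1.31. The 6 higher genes were all HOX genes, HOXB5 among them (3.06, 0.000241), and the 2 lower ones were EN1 and PAX8, the latter by -2.64 (0.00191).

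Genes of CNS progenitors were lower in p75+HNK1+ than in PSA-NCAM-positive cells. Of 17 progenitor genes, 9 were lower, 0 higher and 8 not called, with 10 lower and 1 higher adjusted over the list alone (median -1.14, adjusted p = 4.19e-07, and adjusted p = 0.0570 with an estimated correlation). HES5 differed by -3.56 (0.00657) and PAX6 by -3.55 (0.000116). In the anterior forebrain and eye field list 5 of 8 genes were lower, 0 higher and 3 not called, with 7 lower adjusted over the list alone (median -2.57, or -1.86 at bounds, adjusted p = 5.62e-08, and adjusted p = 0.0536 with an estimated correlation). FEZF2 was at least 4.22-fold lower (0.00290). Among 18 neuron differentiation genes, 6 were lower, 0 higher and 12 not called, with 10 lower adjusted over the list alone (median -1.27, adjusted p = 4.47e-07, and adjusted p = 0.185 with an estimated correlation). STMN2 differed by -3.42 (0.00430) and the NOTCH ligand DLL3 by -2.11 (0.00215).

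NOTCH pathway genes were lower as well. In the NOTCH pathway 10 of 17 genes were lower, 0 higher and 7 not called, with 14 lower adjusted over the list alone (median -1.61, or -1.19 at bounds, adjusted p = 3.86e-11, and adjusted p = 0.0569 with an estimated correlation). HES4 differed by -3.00 (0.000116), DLL1 by -2.72 (0.000461) and MFNG was at least 7.32-fold lower (0.000184). Among 16 WNT response genes 6 were lower, 1 higher and 9 not called, also adjusted over the list alone (median -0.70, or -0.65 at bounds, adjusted p = 0.000144, and adjusted p = 0.134 with an estimated correlation), with SP5 at -4.91 (0.000215). Of 6 surface ectoderm and epithelium genes 4 were lower, 0 higher and 2 not called, with 5 lower and 1 higher adjusted over the list alone (median -2.21, adjusted p = 3.23e-05, and adjusted p = 0.0536 with an estimated correlation), KRT19 being at least 9.07-fold lower (0.000206). The median of this list ran from -2.36 to -0.079 over all settings. Of 17 BMP and TGF-beta response genes 4 were lower, 0 higher and 13 not called, with 8 lower adjusted over the list alone (median -0.93, or -0.81 at bounds, adjusted p = 0.000119, and adjusted p = 0.306 with an estimated correlation).

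Lists not called between p75+HNK1+ and PSA-NCAM-positive cells were sensory and autonomic neuron lineage, with 1 gene lower (adjusted p = 0.489), early mesoderm, with 0 called by limma (0.539), and smooth muscle and contractile genes, with 1 higher and 2 lower (0.217). The others were skeletal muscle, cartilage and bone, with 1 lower (0.254), pluripotency, with 2 higher (0.312), endothelium and blood, with 2 higher and 1 lower (0.489), immediate early and dissociation stress, with 1 higher and 1 lower (0.552), and hypoxia and glycolysis, with 1 lower (0.766). Adjusted over the list alone, early mesoderm had 2 higher and 1 lower, smooth muscle 2 and 4, pluripotency 2 and 2 and endothelium 2 and 3, and the others were the same. None of the 4 Schwann cell and melanocyte genes was called by limma, a list too small to test. The cell cycle list, with 0 of 23 genes called by limma, was not called (median 0.19, 0.0549). It was called higher without PSA-NCAM-positive replicate 2 (0.00782) or 3 (0.0315), without p75+HNK1+ replicate 3 (0.0343), with median scaling (0.0348) and with no filter on dim probes (0.0301).

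In all, 279 genes were higher and 588 lower in p75+HNK1+ than in PSA-NCAM-positive cells (32.2% of called genes higher), and the arrays did not overlap for 27.2% of genes, against 10% by chance. The number of higher genes was 177 without PSA-NCAM-positive replicate 1, 160 without replicate 2 and 508 without replicate 3 of that population, and 128 without p75+HNK1+ replicate 1 and 109 without p75+HNK1+ replicate 3. The number of lower genes was 363 without PSA-NCAM-positive replicate 2, 328 without p75+HNK1+ replicate 1 and 244 without p75+HNK1+ replicate 3.

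PSA-NCAM-negative and p75+HNK1+ cells shared part of the genes in which they differed from PSA-NCAM-positive cells. Of the 1611 and 867 called genes, 237 were higher and 557 lower in both comparisons and 0 were called in opposite directions by limma, where independent calls, without regard to the shared arrays, would give 13.8 and 55.3. Across genes the log2 changes correlated at a Pearson r of 0.899 and a Spearman rho of 0.893, and 87.3% of genes had the same sign. The same 3 PSA-NCAM-positive arrays enter both comparisons. Unchanged groups were simulated with a shared control group, all from residuals of arrays drawn at random, and gave a median r of 0.617 over 100 draws. The outer quantiles of r were -0.10 and 0.868. They are not its extremes, so single draws may lie beyond them. A median of 71.9% of genes had the same sign, with outer quantiles of 42.7% and 85.9%, and a median of 0 genes were called in both. The simulated controls were not fixed to be the PSA-NCAM-positive arrays, so the noise of those arrays was not reproduced. The observed covariance was 0.588 against a simulated median of 0.0716. The changes of p75+HNK1+ cells had 0.806 times the SD of those of PSA-NCAM-negative cells. Leaving out p75+HNK1+ replicate 1 gave an r of 0.845, and leaving out p75+HNK1+ replicate 2 an r of 0.924.

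The third comparison asks how the p75+HNK1+ and PSA-NCAM-negative populations differ from each other. HOX genes were higher in p75+HNK1+ cells: HOXB8 was at 9.44 ± 0.29 (SD, n = 3) against 5.36 ± 0.88 (log2 difference 4.08, adjusted p = 0.00626), HOXB7 was at least 4.64-fold (0.00148) and HOXC8 at least 4.70-fold higher (0.00148), and HOXB5 was higher by 2.89 (0.00390). The progenitor gene SOX3 was at 10.41 ± 0.39 against 6.90 ± 1.06 (3.51, 0.00326). SOX10 was at 10.83 ± 0.38 against 5.81 ± 0.99 (5.02, 0.0353), and B3GAT1 was at 9.23 ± 0.54 against 7.66 ± 0.20 (1.57, 0.0395). ITGA8, an integrin gene, was at least 2.93-fold lower (0.00390).

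Several of these calls were lost when 1 array was left out. Where the call was lost, the difference lay between 4.52 and 5.48 for SOX10, 3.17 and 4.01 for HOXC6, 2.71 and 3.05 for SOX21, 1.28 and 1.65 for B3GAT1, and 1.66 and 1.83 for SNAP25. Other called genes among those with the largest increases were HOXC6 (3.64, adjusted p = 0.0296) and SOX21, a factor of neural progenitors (3.17, 0.0486), with SNAP25, a synaptic gene, at 1.74 (0.0296). Without PSA-NCAM-negative replicate 1 the adjusted p was 0.135 for SOX10, HOXC6, B3GAT1 and SNAP25 and 0.237 for SOX21. Without PSA-NCAM-negative replicate 3 it was 0.0708 for SOX10, 0.140 for HOXC6 and SNAP25, 0.171 for B3GAT1 and 0.234 for SOX21. Without p75+HNK1+ replicate 2 it was 0.200 for SOX10 and HOXC6, 0.246 for B3GAT1, 0.205 for SNAP25 and 0.324 for SOX21, and without p75+HNK1+ replicate 3 it was 0.127 for SOX10 and B3GAT1, 0.0713 for HOXC6, 0.0995 for SNAP25 and 0.204 for SOX21. Leaving out p75+HNK1+ replicate 1 gave 0.0542 for SOX10, 0.0773 for HOXC6 and 0.0678 for SNAP25, and leaving out PSA-NCAM-negative replicate 2 gave 0.0503 for SOX10. Without background correction SOX10 (3.73, 0.0661), SOX21 (2.47, 0.0720), B3GAT1 (1.23, 0.0695) and SNAP25 (1.30, 0.0661) were not called.

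The midbrain, hindbrain and HOX list was higher in p75+HNK1+ cells, and this was the 1 list call that held with an estimated correlation. Of 11 genes, 5 were higher, 0 lower and 6 not called, with 10 higher adjusted over the list alone (median 2.20, or 2.07 at bounds, adjusted p = 1.16e-30, and adjusted p = 0.00325 with an estimated correlation). The 5 were HOXB5, HOXB7, HOXB8 and, named after their values were seen, HOXC4 and PAX8. Over all 10 HOX genes that could be tested, 7 were higher in p75+HNK1+ than in PSA-NCAM-negative cells and 9 higher than in PSA-NCAM-positive cells, and 0 were called by limma between the latter populations. For 9 of the 10, every p75+HNK1+ array lay above the 9 arrays of the other populations. The array has a named probe for 29 HOX genes, and the others did not pass the detection filter. HOXB7, HOXB8, HOXC4, HOXC8 and HOXC9 passed it only through the p75+HNK1+ arrays. These counts are thus partly set by the filter and are no separate test. The list was also called with no filter (camera adjusted p at most 1.16e-16 over the settings tested at the preset correlation).

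Genes of CNS progenitors were higher in p75+HNK1+ than in PSA-NCAM-negative cells. Of 17, 2 were higher (SOX3 and SOX21), 0 lower and 15 not called, with 9 higher adjusted over the list alone (median 0.86, adjusted p = 5.18e-13, and adjusted p = 0.0536 with an estimated correlation). HES5 differed by 3.28 and was not called (0.0851). It was called with the replicate number as a block (0.0331), but that number is only the order of listing. Of 18 neuron differentiation genes 1 was higher, 0 lower and 17 not called, with 8 higher adjusted over the list alone (median 1.18, or 0.79 at bounds, adjusted p = 8.54e-15, and adjusted p = 0.0569 with an estimated correlation). Its largest difference, in the neurofilament gene NEFM, was 3.02 and not called (0.0709), but it was called with median scaling (0.0238) and without PSA-NCAM-negative replicate 2 (0.00236). In the NOTCH pathway 0 of 17 genes were called by limma and 5 were higher adjusted over the list alone (median 0.31, or 0.18 at bounds, adjusted p = 2.89e-06, and adjusted p = 0.126 with an estimated correlation). Among 16 WNT response genes 0 were called by limma and 3 were higher adjusted over the list alone (median 0.46, adjusted p = 7.06e-06, and adjusted p = 0.0793 with an estimated correlation). The anterior forebrain and eye field list, with 0 of 8 genes called by limma and 2 higher adjusted over the list alone, was not called (median 0.14, or 0.00 at bounds, 0.105).

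Of 24 neural crest genes, 2 were higher, 0 lower and 22 not called, with 5 higher adjusted over the list alone (median 0.27, or 0.17 at bounds, adjusted p = 0.000144, and adjusted p = 0.0570 with an estimated correlation). The 2 were SOX10 and CDH19, a cadherin of crest-derived glia, at least 2.47-fold higher (0.00967). The CDH19 call was lost without PSA-NCAM-negative replicate 3 (0.0517), p75+HNK1+ replicate 2 (0.0662) and p75+HNK1+ replicate 3 (0.0713), and with genes detected on all 12 arrays the list was not called (0.395). That filter drops CDH19, which was detected on no PSA-NCAM-negative array, and the SOX10 probe used here. TFAP2A differed by -0.24 and SNAI2 by -0.03 (adjusted p = 1 for each), members named after their values were seen. The antigen list was higher, with 1 of 6 genes called, also adjusted over the list alone (median 0.35, adjusted p = 0.00140, and adjusted p = 0.0827 with an estimated correlation). NGFR differed by 0.15, ST8SIA2 by 0.43 and NCAM1 by 0.27 (adjusted p = 1 for each), and none of them was called.

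The immediate early and dissociation stress list was lower in p75+HNK1+ than in PSA-NCAM-negative cells, with 0 of 17 genes called by limma (median -0.58, adjusted p = 0.000246, and adjusted p = 0.437 with an estimated correlation). So was hypoxia and glycolysis, with 0 of 15 genes called by limma (median -0.29, adjusted p = 0.0387, and adjusted p = 0.634 with an estimated correlation). PSA-NCAM-negative replicate 2 stood above the other arrays of its population by 1.18 in the first list, with 15 of 17 members above, and by 1.33 in the second, with 15 of 15. Without it the medians were 0.03 (0.855) and 0.22 (0.177), in the opposite direction. The hypoxia call was also lost without p75+HNK1+ replicate 2 (0.344) or 3 (0.394, median 0.03) and with no filter on dim probes (0.169). Mesenchyme and extracellular matrix, with 0 of 31 genes called by limma and 1 higher adjusted over the list alone, was higher (median 0.12, adjusted p = 0.0494, and adjusted p = 0.565 with an estimated correlation). That call was lost without PSA-NCAM-negative replicate 1 (0.308) or 3 (0.837), without p75+HNK1+ replicate 1 (0.0758) or 2 (0.115), with median scaling (0.1), with no filter on dim probes (0.0885) and with genes detected on all 12 arrays (0.314).

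Not called between these populations were surface ectoderm and epithelium (adjusted p = 0.823), sensory and autonomic neuron lineage (0.268), early mesoderm (0.354), skeletal muscle, cartilage and bone (0.489), endothelium and blood (0.390) and cell cycle (0.867), with 0 genes called by limma in each, also adjusted over the list alone. Neither were smooth muscle and contractile genes (0.352), called lower without PSA-NCAM-negative replicate 2 (0.0325), nor BMP and TGF-beta response genes (0.390), called higher without PSA-NCAM-negative replicate 2 (0.000144) and without p75+HNK1+ replicate 3 (0.0319). Pluripotency genes (median 0.57, 0.0529) were called higher without PSA-NCAM-negative replicate 1 (0.0170), without p75+HNK1+ replicate 3 (0.0264), without background correction (0.0393) and with genes detected on all 12 arrays (0.0172).

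In all, 27 genes were higher and 3 lower in p75+HNK1+ than in PSA-NCAM-negative cells (90% of called genes higher), with 511 genes at an unadjusted p under 0.05 where chance gives 561.5, and the arrays did not overlap for 9.92% of genes, against 10% by chance. With median scaling, under which the median of all genes was 0.15 instead of 0.01, 44 were higher. The number of higher genes was 9 without PSA-NCAM-negative replicate 1, 88 without replicate 2 and 8 without replicate 3 of that population, and 7 without p75+HNK1+ replicate 2 or 3. The number of lower genes was 6 without PSA-NCAM-negative replicate 2, 1 without PSA-NCAM-negative replicate 3, 5 without p75+HNK1+ replicate 1 and 1 without p75+HNK1+ replicate 2. With genes detected on all 12 arrays, 0 genes were called by limma.

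**Figure D3:**
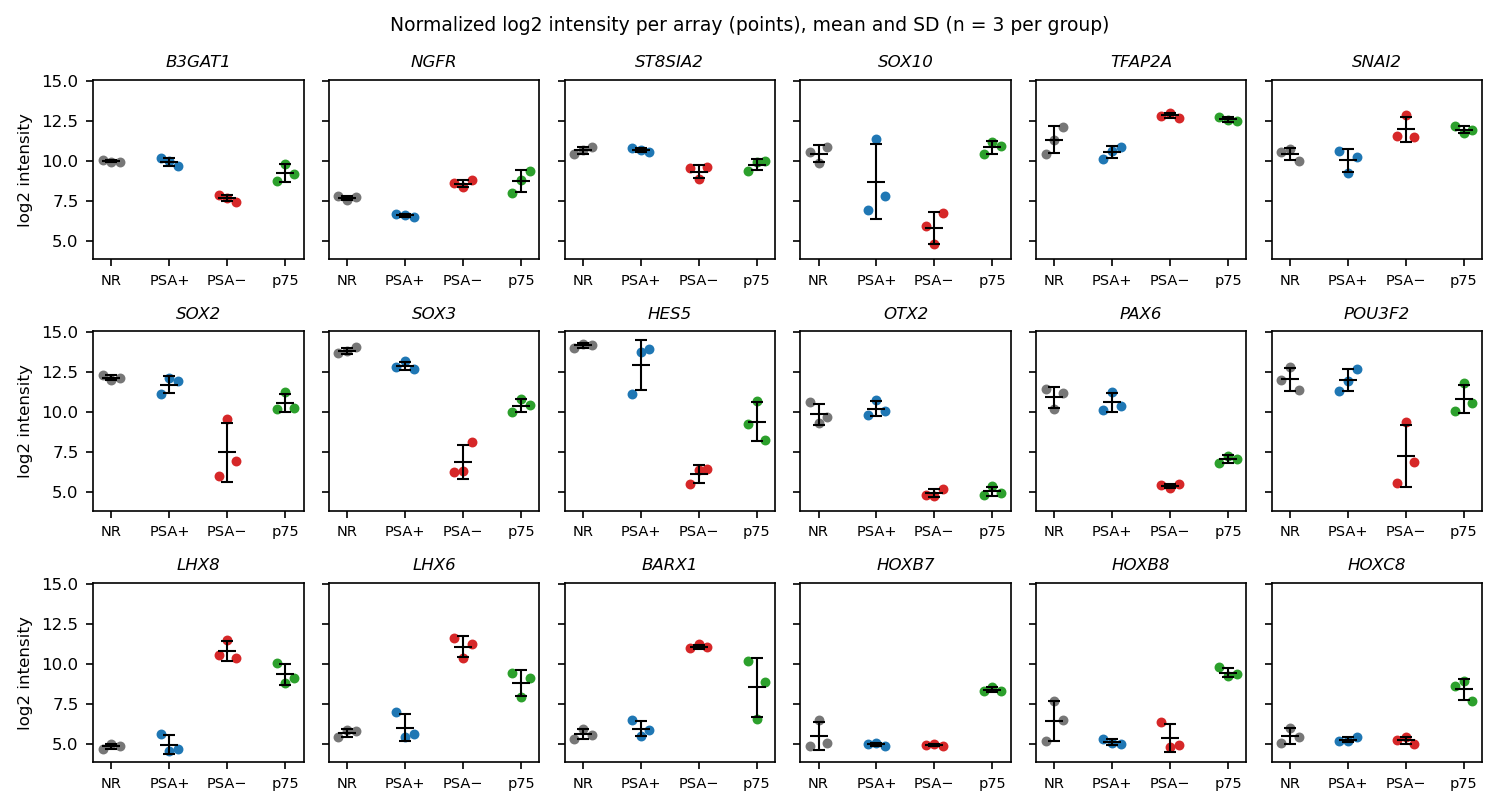
Normalized log2 intensity of 18 genes in neural rosettes (NR), PSA-NCAM-positive (PSA+), PSA-NCAM-negative (PSA−) and p75+HNK1+ (p75) cells; each point is 1 array, and the bar and whiskers are the mean and SD of 3 arrays. HOXB7, HOXB8 and HOXC8 are highest on the p75+HNK1+ arrays, and LHX8, LHX6 and BARX1 are higher in PSA-NCAM-negative than in PSA-NCAM-positive cells.

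The secondary comparisons set each isolated population against neural rosettes. PSA-NCAM-positive cells differed from rosettes in few called genes, with 0 genes higher and 4 lower by limma and 757 at an unadjusted p under 0.05 where chance gives 561.5. VTCN1, an immune checkpoint gene, was at least 2.96-fold lower (adjusted p = 0.0165), the neuropeptide gene ADCYAP1 at least 2.52-fold (0.0165), and the WNT antagonist SOST and the coagulation factor gene F3 differed by -2.59 (0.0212) and -1.94 (0.0306). Each of these calls was lost when certain arrays were left out. Without rosette replicate 1 the adjusted p was 0.129 for ADCYAP1, 0.181 for SOST and 0.187 for F3, and without rosette replicate 3 it was 0.139 for SOST and 0.0794 for F3. Without PSA-NCAM-positive replicate 3 it was 0.0617 for VTCN1, ADCYAP1 and F3, without replicate 2 of that population 0.0542 for SOST and 0.0716 for F3, and without replicate 1 it was 0.0672 for F3.

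Lists were lower in PSA-NCAM-positive cells than in rosettes although 0 of their genes were called by limma. These list calls come from the same fit as the gene calls, which takes the arrays as independent. For sensory and autonomic neuron lineage, 5 of 7 genes were lower adjusted over the list alone (median -1.73, or -0.60 at bounds, adjusted p = 4.47e-07, and adjusted p = 0.0536 with an estimated correlation). NEUROG2, a proneural factor, differed by -2.69 (0.1), and the sensory neuron factors ISL1 and POU4F1 by -2.15 (0.180) and -2.14 (0.187). Neural crest (median -0.38, or -0.33 at bounds, adjusted p = 0.000337, and adjusted p = 0.0665 with an estimated correlation) and NOTCH pathway genes (median -0.40, adjusted p = 0.000941, and adjusted p = 0.296 with an estimated correlation) were also lower. CNS neural progenitor genes were lower (median -0.31, adjusted p = 0.00514, and adjusted p = 0.287 with an estimated correlation), a call lost without rosette replicate 1 (0.0642) and PSA-NCAM-positive replicate 1 (0.257). So were immediate early and dissociation stress genes (median -0.55, adjusted p = 0.00159, and adjusted p = 0.474 with an estimated correlation), lost without PSA-NCAM-positive replicate 3 (0.148). The midbrain, hindbrain and HOX list (median -0.27, or -0.15 at bounds, adjusted p = 0.0276, and adjusted p = 0.300 with an estimated correlation) lost its call without rosette replicate 2 (0.371) or 3 (0.103) and without PSA-NCAM-positive replicate 2 (0.0988) or 3 (0.0996).

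The arrays of PSA-NCAM-positive cells and rosettes did not overlap for 8.95% of genes, against 10% by chance, a share that, like the fit, takes the arrays as independent. The number of lower genes was 1 without rosette replicate 1, 28 without rosette replicate 2, 2 without rosette replicate 3, 8 without PSA-NCAM-positive replicate 1, 7 without PSA-NCAM-positive replicate 2 and 2 without PSA-NCAM-positive replicate 3. That of higher genes was 1 without rosette replicate 2 and 2 without PSA-NCAM-positive replicate 2. Among lists not called, anterior forebrain and eye field was called lower without rosette replicate 2 (adjusted p = 0.0109) or PSA-NCAM-positive replicate 2 (0.0317), and cell cycle was called higher without rosette replicate 2 (0.0205) or PSA-NCAM-positive replicate 1 (0.000446). Hypoxia and glycolysis was called higher without rosette replicate 3 (0.00718) or PSA-NCAM-positive replicate 2 (0.0170), WNT response lower without rosette replicate 2 (0.0423), early mesoderm higher without PSA-NCAM-positive replicate 2 (0.0317) and smooth muscle and contractile lower without PSA-NCAM-positive replicate 1 (0.0421).

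Next, PSA-NCAM-negative cells were set against rosettes. LHX8 was at 10.80 ± 0.61 (SD, n = 3) against 4.85 ± 0.16, at least 27.5-fold higher (adjusted p = 1.79e-06), BARX1 at least 32.8-fold higher (0.000100) and TBX2 higher by 4.21 (0.00273). HES5 was at 6.12 ± 0.55 against 14.17 ± 0.15 (-8.05, 9.26e-06), WNT3A at least 88.2-fold lower (6.73e-07), and CXCR4, a chemokine receptor of migrating cells, at least 32.8-fold lower (1.27e-05). B3GAT1 differed by -2.31 (0.000103) and ST8SIA2 by -1.33 (0.00310), while NGFR differed by 0.89 and was not called (0.0644).

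Of 17 CNS progenitor genes, 14 were lower, 1 higher and 2 not called, also adjusted over the list alone (median -3.19, adjusted p = 3.25e-12, and adjusted p = 0.0536 with an estimated correlation), and 7 of 8 anterior genes were lower, also adjusted over the list alone (median -3.14, adjusted p = 2.52e-07, and adjusted p = 0.0569 with an estimated correlation). Of 18 neuron differentiation genes 16 were lower, with 17 adjusted over the list alone (median -2.29, or -2.21 at bounds, adjusted p = 2.19e-12, and adjusted p = 0.0665 with an estimated correlation). NOTCH pathway genes were lower in 12 of 17 cases, 15 adjusted over the list alone (median -2.51, or -2.16 at bounds, adjusted p = 8.96e-13, and adjusted p = 0.0536 with an estimated correlation), and WNT response genes in 11 of 16, with 1 higher, or 13 and 2 adjusted over the list alone (median -1.75, adjusted p = 2.09e-07, and adjusted p = 0.0569 with an estimated correlation). Sensory and autonomic neuron lineage had 6 of 7 genes lower and 1 higher, also adjusted over the list alone (median -3.03, or -2.45 at bounds, adjusted p = 0.000451, and adjusted p = 0.0569 with an estimated correlation), POU4F1 being at least 9.61-fold lower (0.000129) and EYA1, a placode and mesenchyme gene, higher by 3.15 (0.00207).

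Surface ectoderm and epithelium had 5 of 6 genes lower, also adjusted over the list alone (median -2.08, or -1.68 at bounds, adjusted p = 0.000341, and adjusted p = 0.0569 with an estimated correlation). Midbrain, hindbrain and HOX had 4 of 11 lower, or 5 adjusted over the list alone (median -1.08, adjusted p = 0.000782, and adjusted p = 0.114 with an estimated correlation), and BMP and TGF-beta response 4 of 17, or 7 adjusted over the list alone (median -0.77, or -0.56 at bounds, adjusted p = 0.00489, and adjusted p = 0.473 with an estimated correlation), the latter with replicate 2 of PSA-NCAM-negative cells standing 1.01 above the others. Mesenchyme and extracellular matrix had 6 of 31 genes higher and 1 lower, or 9 and 1 adjusted over the list alone (median 0.81, adjusted p = 0.00514, and adjusted p = 0.473 with an estimated correlation), a call lost without PSA-NCAM-negative replicate 2 (0.239). Cell cycle had 2 of 23 genes higher, and 0 by limma adjusted over the list alone (median 0.29, adjusted p = 0.0232, and adjusted p = 0.516 with an estimated correlation), lost without rosette replicate 3 (0.110) and PSA-NCAM-negative replicate 1 (0.103). The neural crest list split again, with 7 of 24 genes higher and 7 lower, or 9 and 9 adjusted over the list alone, and was not called (median 0.23, mean -0.51, 0.867). SOX10 was among the lower ones (-4.63, 0.00249). With genes detected on all 12 arrays the crest list was called higher (0.0325), but that filter drops lower members at background in PSA-NCAM-negative cells, such as the SOX10 probe used here. Hypoxia and glycolysis, not called (0.143), was called higher without rosette replicate 3 (0.0382), PSA-NCAM-negative replicate 1 (0.0157) or PSA-NCAM-negative replicate 3 (0.0369) and with median scaling (0.0475). Immediate early and dissociation stress, not called (0.578), was called lower without PSA-NCAM-negative replicate 2 (0.00845).

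In all, 734 genes were higher and 1181 lower in PSA-NCAM-negative cells than in rosettes (38.3% higher), and the arrays did not overlap for 34.1% of genes, against 10% by chance. With median scaling, under which the median of all genes was -0.18 instead of 0.01, 361 were higher and 1556 lower (18.8% higher). The number of higher genes was 481 without rosette replicate 1, 396 without PSA-NCAM-negative replicate 1 and 470 without PSA-NCAM-negative replicate 3.

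Single HOX genes were higher in p75+HNK1+ cells than in rosettes, and OTX1 and LMX1A were among the genes with the largest decrease. HOXB8 was at 9.44 ± 0.29 (SD, n = 3) against 6.44 ± 1.25 (3.00, adjusted p = 0.00346) and HOXB7 was higher by 2.91 (0.000263). FGFBP2, a secreted protein gene, was at least 14.7-fold higher (0.00397), and COL12A1, a collagen gene, by 3.36 (0.00409). OTX1, a forebrain factor, was at least 26.1-fold lower (2.60e-05), LMX1A, a roof plate gene, at least 16-fold lower (3.82e-06), and PAX6 differed by -3.86 (3.36e-05). NGFR differed by 1.04 (0.0493) and ST8SIA2 by -0.91 (0.0410). The NGFR call was lost without rosette replicate 1 (0.0917), 2 (0.0996) or 3 (0.110) and without p75+HNK1+ replicate 2 (0.131) or 3 (0.225), and that of ST8SIA2 without rosette replicate 1 (0.0584), 2 (0.0741) or 3 (0.135) and p75+HNK1+ replicate 1 (0.169), 2 (0.0692) or 3 (0.0764). With median scaling neither was called (0.103 for NGFR and 0.0797 for ST8SIA2).

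Of 24 neural crest genes, 8 were higher, 3 lower and 13 not called, with 10 higher and 3 lower adjusted over the list alone (median 0.79, or 0.62 at bounds, adjusted p = 0.0397, and adjusted p = 0.287 with an estimated correlation), a call lost without rosette replicate 1 (0.0789), rosette replicate 2 (0.0744) and p75+HNK1+ replicate 2 (0.142). Mesenchyme and extracellular matrix had 7 of 31 genes higher and 1 lower, with 11 and 1 adjusted over the list alone (median 0.86, adjusted p = 3.79e-05, and adjusted p = 0.287 with an estimated correlation). The midbrain, hindbrain and HOX list, with 6 of 11 genes higher and 2 lower, or 6 and 3 adjusted over the list alone, was not called (median 1.04, or 0.86 at bounds, 0.0675), but was without rosette replicate 2 (0.0211), without p75+HNK1+ replicate 3 (0.0406) and with median scaling (0.0340). Cell cycle was higher with 0 of 23 genes called by limma (median 0.26, adjusted p = 0.00573, and adjusted p = 0.473 with an estimated correlation).

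CNS progenitor genes were lower in 9 of 17 cases, or 12 with 1 higher adjusted over the list alone (median -1.55, adjusted p = 2.70e-09, and adjusted p = 0.0536 with an estimated correlation), and anterior genes in 6 of 8, or 7 adjusted over the list alone (median -3.44, or -3.04 at bounds, adjusted p = 6.46e-08, and adjusted p = 0.0536 with an estimated correlation). Neuron differentiation had 8 of 18 genes lower, or 11 adjusted over the list alone (median -1.37, adjusted p = 4.28e-07, and adjusted p = 0.185 with an estimated correlation) and sensory and autonomic neuron lineage 6 of 7, with 1 higher, also adjusted over the list alone (median -2.46, adjusted p = 0.000245, and adjusted p = 0.0569 with an estimated correlation). The NOTCH pathway had 11 of 17 lower, or 14 adjusted over the list alone (median -1.96, or -1.85 at bounds, adjusted p = 5.18e-13, and adjusted p = 0.0536 with an estimated correlation), with LFNG, which modifies NOTCH receptors, at -3.13 (1.02e-05). WNT response had 9 of 16 lower and 1 higher, also adjusted over the list alone (median -1.09, adjusted p = 5.43e-06, and adjusted p = 0.0775 with an estimated correlation). Surface ectoderm and epithelium had 5 of 6 lower, also adjusted over the list alone (median -1.76, adjusted p = 3.55e-05, and adjusted p = 0.0536 with an estimated correlation) and BMP and TGF-beta response 3 of 17, or 5 adjusted over the list alone (median -0.92, or -0.69 at bounds, adjusted p = 0.00510, and adjusted p = 0.473 with an estimated correlation). Immediate early and dissociation stress had 2 of 17 lower, also adjusted over the list alone (median -0.75, adjusted p = 0.0233, and adjusted p = 0.567 with an estimated correlation), a call lost without rosette replicate 1 (0.0657) and p75+HNK1+ replicate 2 (0.0515).

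In all, 385 genes were higher and 749 lower in p75+HNK1+ cells than in rosettes (34.0% higher), and 242 and 856 with median scaling (22.0% higher). The arrays did not overlap for 35.8% of genes, against 10% by chance. The number of higher genes was 201 without rosette replicate 1, 223 without rosette replicate 3, 157 without p75+HNK1+ replicate 1, 223 without p75+HNK1+ replicate 2 and 144 without p75+HNK1+ replicate 3. That of lower genes was 451 without rosette replicate 3, 459 without p75+HNK1+ replicate 1 and 402 without p75+HNK1+ replicate 3.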

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

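Counts of called genes moved most with the filter, with left-out arrays and with array weights, and 2 list results turned. Requiring detection on all 12 arrays tests 9213 genes in place of 11230 and gave 320 higher and 522 lower genes for PSA-NCAM-negative minus PSA-NCAM-positive, 118 and 218 for p75+HNK1+ minus PSA-NCAM-positive, 0 and 0 for p75+HNK1+ minus PSA-NCAM-negative, 0 lower for PSA-NCAM-positive minus rosettes, 475 and 575 for PSA-NCAM-negative minus rosettes, and 168 and 275 for p75+HNK1+ minus rosettes. It drops genes at background in 1 population. With no filter (20046 genes) p75+HNK1+ minus PSA-NCAM-negative had 13 higher genes and PSA-NCAM-positive minus rosettes 1 higher and 11 lower. Median scaling gave 344 higher genes for PSA-NCAM-negative minus PSA-NCAM-positive, 44 for p75+HNK1+ minus PSA-NCAM-negative, 361 for PSA-NCAM-negative and 242 for p75+HNK1+ minus rosettes, and 1 higher and 9 lower for PSA-NCAM-positive minus rosettes. Log2 quantile normalization and the value table of the authors, nearly the same by construction, gave 13 higher genes for p75+HNK1+ minus PSA-NCAM-negative. With only the 6 arrays compared there were 8 higher and 1 lower in that comparison and 1 lower for PSA-NCAM-positive minus rosettes. The replicate number as a block gave 52 higher genes for p75+HNK1+ minus PSA-NCAM-negative and 246 for p75+HNK1+ minus rosettes. Except for the filter, which tests fewer or more genes, and the 6 arrays, which are fewer, the cause was not tested. Array weights, chosen after seeing the data, gave 1636 and 1890, 1326 and 1383, 293 and 45, 57 and 122, 1922 and 2038, and 1679 and 1758 in the same order of comparisons, with weights from 0.283 to 3.43, but the fit of the weights stopped before it reached its tolerance. A lower limit of 2-fold and every probe on its own left each count within 1.5 times.

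Leaving out 1 array at a time gave 344 to 939 higher and 729 to 1284 lower genes for PSA-NCAM-negative minus PSA-NCAM-positive, 109 to 508 and 244 to 652 for p75+HNK1+ minus PSA-NCAM-positive, 7 to 88 and 1 to 6 for p75+HNK1+ minus PSA-NCAM-negative, 0 to 2 and 1 to 28 for PSA-NCAM-positive minus rosettes, 396 to 859 and 812 to 1229 for PSA-NCAM-negative minus rosettes, and 144 to 515 and 402 to 725 for p75+HNK1+ minus rosettes. The correlation of the changes against PSA-NCAM-positive cells ran from 0.845 to 0.924. Without PSA-NCAM-negative replicate 2, on which both lists stood high, the list immediate early and dissociation stress turned in p75+HNK1+ minus PSA-NCAM-negative (median 0.0256), with medians from -0.918 to 0.0256 over the left-out arrays. The list hypoxia and glycolysis turned with it (0.224), with medians from -0.707 to 0.224. Over the alternatives, list results kept direction and side of the threshold in 1350 cases, lost the call in 88, gained it in 37, moved without a call in 47 and turned in 2, and 57 of the 88 losses came with an estimated correlation. Named genes kept both in 5039 cases, lost the call in 289, gained it in 72, moved in 60 and turned in 0. The replicate block lost the calls of 1 list (hypoxia and glycolysis in p75+HNK1+ minus PSA-NCAM-negative, 0.0533) and of 11 named-gene results, among them ST8SIA2 in p75+HNK1+ minus PSA-NCAM-positive (0.0792) and minus rosettes (0.0739), NGFR in p75+HNK1+ minus rosettes (0.0794) and F3 in PSA-NCAM-positive minus rosettes (0.123). It gained 9, among them HES5 (0.0331) and NEFM (0.0399) in p75+HNK1+ minus PSA-NCAM-negative, and changed no other list or named gene. The replicate numbers only follow the order of listing, so the block and a check of same-number samples test no known pairing. By these numbers, 6 of 18 same-number correlations of array deviations were over 0.1 (from -0.582 to 0.261), and 1 of 12 samples matched its own number best. The slide as a block was not run, since the files give no slide. Between 34.5% and 38.8% of probes lay above background per array, so changes in dim genes are given as bounds.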

Other observations

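The tests of carry-over and of PSA-NCAM-negative replicate 2 for the CNS genes, of mixing for the HOX genes, and of handling stress for the immediate early genes were chosen after the results were seen, and so were the added gene lists.

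In a list of dorsal neural tube genes added after many of its values had been seen, 12 of 13 measured genes were lower in PSA-NCAM-negative and 11 in p75+HNK1+ than in PSA-NCAM-positive cells by limma (medians -4.60 and -3.47), and 0 were called between PSA-NCAM-negative and p75+HNK1+ cells or between PSA-NCAM-positive cells and rosettes. RSPO1, a WNT agonist of the roof plate, was at 4.82 ± 0.12 (SD, n = 3) in PSA-NCAM-negative, 4.83 ± 0.30 in p75+HNK1+ and 9.88 ± 0.63 in PSA-NCAM-positive cells. Of 9 ventral neural tube genes 1 could be tested, OLIG2, which differed by 0.30 between PSA-NCAM-negative and PSA-NCAM-positive cells and was not called.

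In a list of pharyngeal arch mesenchyme genes added in the same manner, 10 of 12 measured genes were higher in PSA-NCAM-negative and 6 in p75+HNK1+ than in PSA-NCAM-positive cells (medians 3.15 and 2.47), and 9 were higher in each than in rosettes. Between p75+HNK1+ and PSA-NCAM-negative cells 0 were called by limma (median -0.96). TBX2, a T-box factor of the arches, was at 10.95 ± 1.00 in PSA-NCAM-negative and 7.21 ± 1.97 in PSA-NCAM-positive cells. Since genes of both lists were picked from these values, the counts describe them and are no test.

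Of 17 CNS progenitor genes 2 were higher in p75+HNK1+ than in PSA-NCAM-negative cells and 15 not called, and the list was higher (median 0.86, adjusted p = 5.18e-13, and adjusted p = 0.0536 with an estimated correlation), which might come from PSA-NCAM-positive cells carried over in the sort. On the linear scale, over genes at least 4-fold lower in PSA-NCAM-negative cells, p75+HNK1+ arrays covered a median of 31.8 ± 25.4% (SD, n = 3) of the difference between PSA-NCAM-negative and PSA-NCAM-positive levels for 8 progenitor genes, 11.8% on the lowest array, and 0.319 ± 0.497% for 7 anterior genes, 0.891% on the highest array. There LHX2, OTX2 and PAX6, members of both lists, were counted as anterior only, and OTX1, a member of neither, was added; with every member of each list the medians were 20.2 ± 10.9% for 11 progenitor and 0.859 ± 0.324% for 6 anterior genes. Single genes overlapped, from -40.5% for LHX2 to 22.9% for EMX2 among the anterior and from 7.33% for HES5 to 97.0% for SOX21 among the progenitor genes. Over all 382 genes at least 4-fold lower, looked at after these values were seen, the median p75+HNK1+ level was 15.2%, 33.2% and 18.4% of the PSA-NCAM-positive level on replicates 1 to 3, in the same array order as the progenitor shares of 11.8%, 60.3% and 23.3%, while 126 genes lay below those shares on every array. For PSA-NCAM-negative replicate 2 alone to be the source, that array would have to stand low in this list. It stood 0.31 above the other arrays of its population, with 9 of 17 members above. Leaving it out could thus be foreseen to raise the median, and is no separate test. Without it the median was 0.97 (camera adjusted p = 5.10e-14, and adjusted p = 0.0816 with an estimated correlation). Carried-over cells like the PSA-NCAM-positive average, mixed with cells like the PSA-NCAM-negative average, are argued against as the whole source. Of 176 abundant genes outside the progenitor list, 20 lay below that mixture at the lowest share the list needed, 11.6% (adjusted p under 0.05, median -1.92). Among them were OTX1, RSPO1 and WNT3A, and with the lowest PSA-NCAM-positive array in place of the mean 9 genes lay below. The mixture takes the other cells of the sort to be like PSA-NCAM-negative cells. A gene lower in them than in PSA-NCAM-negative cells could also fall below it, which was not tested. The median of the 176 was 0.07 from that mixture and 0 lay above it by the same test, so carry-over of a smaller share or of a subset of cells cannot be told apart from a real difference between the populations.

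Of 8 tested HOX genes of paralog groups 4 to 9, 7 were higher in p75+HNK1+ than in PSA-NCAM-negative cells, while HOXB6 was not called (0.93, adjusted p = 0.381), and for 8 of 8 every p75+HNK1+ array lay above the 9 others. HOXB2, tested but of paralog group 2 and so outside this set, did not have every p75+HNK1+ array above the others. Mixing with cells like the average of another population cannot give levels above all of them. Carry-over of a subset of cells with higher HOX levels could, and was not tested. Since the pattern was chosen for these levels, the 8 of 8 is no separate test. The detection filter also favoured it, since HOXB7, HOXB8, HOXC4, HOXC8 and HOXC9 passed only through the p75+HNK1+ arrays. Between-array scaling is argued against by a median difference from PSA-NCAM-negative cells of at least 1.93 under each of 4 normalizations (at most 3.11). The labels and files name no culture or array batch, so none was weighed, and a difference between the sorted populations stays open and untested.

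Immediate early genes stood 1.18 higher on PSA-NCAM-negative replicate 2 than on the other arrays of its population, with hypoxia genes at 1.33 and, in an added list, small nuclear RNAs at 3.20, 9 of 9 above. The lower overall signal of that array is argued against by a median of at least 0.69 under each of 4 normalizations, of which only median scaling is not a quantile normalization. The list lay at percentile 100 of 10000 random lists matched on expression, which is what handling stress of that sample could give. The random lists were drawn gene by gene, so any joint shift of the list on that array, whatever its cause, gives a high percentile. The labels record no handling, so handling stress cannot be told apart from a difference of the cells. No biological explanation was tested, since the design sets no factor within the population.

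With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave the most called genes, 1 of 10, in 5 comparisons: 1611 against at most 0 for PSA-NCAM-negative minus PSA-NCAM-positive, 867 against 1 for p75+HNK1+ minus PSA-NCAM-positive, 30 against 0 for p75+HNK1+ minus PSA-NCAM-negative, 1915 against 0 for PSA-NCAM-negative minus rosettes and 1134 against 0 for p75+HNK1+ minus rosettes. For PSA-NCAM-positive minus rosettes 2 of 10 splits gave as many, with 4 genes for the real one and 384 for rosette replicates 1 and 2 with PSA-NCAM-positive replicate 3 against the rest. That count points to a structure of the samples: across genes, deviations from the population means correlated at 0.743 for rosette replicate 2 with PSA-NCAM-positive replicate 3, at 0.507 for rosette replicate 3 with PSA-NCAM-positive replicate 1 and at 0.307 for rosette replicate 1 with PSA-NCAM-positive replicate 2. The structure was not confined to these populations. PSA-NCAM-negative replicate 1 correlated with p75+HNK1+ replicate 3 at 0.379, and rosette replicate 3 with p75+HNK1+ replicate 1 at 0.337. The count of 4, like the other counts and list calls, comes from a fit without these pairs. The pairs were found in the same values and are not in the labels.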
